A study of Homo sapiens with 6 samples.

How the data were processed

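RNA of 12Z cells was measured in 6 libraries, 3 transfected with an siRNA against SMARCA4 and 3 with a non-targeting siRNA. Per the labels' protocols, cells grown in 10% serum were transfected with 50 nM siRNA, the medium was changed at 24 h and, to 0.5% serum, at 48 h, and RNA was extracted at 72 h. Directional mRNA libraries were made from 500 ng of total RNA, per the labels, which state the same kit for all samples. The labels of the 3 control samples mark them as analysed again from an earlier deposit, and the 3 siBRG1 samples carry no such mark.

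For each library the authors deposited a table of raw counts per gene, in the layout STAR writes, with unstranded, sense and antisense counts. The submitters' processing notes name cutadapt, Trim Galore, FastQC, STAR and DESeq2 without versions, and genome build GRCh38.p12. The gene annotation release is not given in the sources used here. Of 58336 gene identifiers, 56888 matched GENCODE release 29 with their version and 58216 without it, and symbols, gene types and coordinates on GRCh38 were taken from that release. A table of the whole series, which the authors deposited beside the counts, holds their own comparison of the groups. Per the file headers it gives a mean signal over libraries normalised by size factors, a log2 fold change with its standard error and a shrunken form, and a p-value with Benjamini-Hochberg and IHW adjusted forms. That mean signal was not recovered from the counts and is not used here. The authors' table lists genes by symbol, and its values are given only where the text names it.

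The stranded column with the larger total in every library was taken as the sense count and used for all main results. Antisense counts made up 6.03 ± 0.0826% of stranded counts in siBRG1 and 6.16 ± 0.0202% in control (SD, n = 3). Entries that name no gene were left out of library sizes and tests. They held 1.84 ± 0.0732% (unmapped), 20.3 ± 1.62% (several places), 3.97 ± 0.194% (no feature) and 3.11 ± 0.0288% (ambiguous) of all reads in siBRG1. In control they held 1.64 ± 0.0678%, 9.81 ± 0.224%, 13.3 ± 0.415% and 4.16 ± 0.0271%. All reads came to 18014200 ± 422301 per siBRG1 library and 61675900 ± 7692820 per control library. At these depths 3 counts stand for 0.230 CPM in an siBRG1 library and 0.0710 CPM in a control library on average. The 10 most abundant genes took 4.40 ± 0.0525% of gene counts in siBRG1 and 4.23 ± 0.0519% in control.

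Replicates were compared before they were averaged. Counts of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 2.52 to 4.24), so all 6 were kept as separate libraries. Log2 CPM correlated across genes at r = 0.984 to 0.985 among siBRG1 libraries, 0.996 among control libraries and 0.923 to 0.931 between groups.

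Groups were compared with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr and robust quasi-likelihood fits on an intercept and the group. Tests were two-sided, and an adjusted p (Benjamini-Hochberg) under 0.05 counted as a call. Of the genes, 15830 passed the filter, and the common dispersion was 0.00171. The SE of a log2 fold change was taken as its absolute value over the square root of the F statistic. Shares of reads and counts were compared with exact two-sided permutation tests of the difference in means, where 3 libraries against 3 allow no p below 0.1. A fold against a group at 0 counts was computed against a floor of 3 counts over the group. Ratios that rest on 1 to 3 counts carry an exact 95% interval for counting.

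The gene lists, the rule for named genes and a set of alternatives were fixed before the data were examined. The 23 lists covered SWI/SNF subunits, epithelial junctions and polarity, keratins, mesenchymal genes, collagens and basement membrane, integrins, matrix proteases, TGF-beta/SMAD targets, YAP/TAZ targets, AP-1 and immediate early genes, cell cycle, p53 targets, interferon response, NF-kappaB and cytokines, cholesterol synthesis, ATF4 and unfolded protein response, hypoxia and glycolysis, Mullerian and hormone genes, stromal cell markers, endothelial and immune markers, mitochondrial transcripts, ribosomal proteins and replication histones. Each with at least 5 tested members was tested with camera of limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. COL3A1, THY1, TGFB2, JUNB, SESN2 and ATF3 are among the genes that stand in more than 1 list.

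The rule for named genes took SMARCA4 and SMARCA2; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 100 counts and no overlap of CPM between groups; and of each list up to 2 members (up to 4 for the epithelial and mesenchymal lists) with the largest change among those past the threshold with a mean of at least 50 counts, the largest of each direction first. Members named because a count came to 5 or fewer, and genes said to be singled out, were chosen after their values were seen. Some genes that the rule takes are not reported here.

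The procedure was tested on simulated data drawn from the real means and library sizes of 15830 genes. At true folds of 1.25, 1.5, 2 and 4, with 50 genes each, 62%, 70%, 72% and 96% of the changed genes were called. Of 173 calls 5 were false (2.89%), and camera called the 1 list that was changed and 0 of 19 that were not, at an adjusted p under 0.05. Genes were drawn independently and few were changed, unlike in the data, where estimated correlations within lists reached 0.818. The simulation therefore does not test camera's calls on lists of correlated genes.

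The alternatives set at that point were DESeq2 size factors in place of TMM, no filter on low counts, a filter of at least 50 counts in 3 libraries, unstranded counts, the replicate number as a block, all libraries thinned to the shallowest total, and GC and length trends of each library removed as offsets (natural splines, 5 degrees of freedom). The offsets were also run together with the block. DESeq2's Wald test (DESeq2 1.42.0), limma voom and leaving out each library in turn completed that set. A fit of protein-coding genes alone, without histones and mitochondrial genes and normalised anew, was added after the data were seen.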

Results

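RNA sequencing was used to compare 12Z cells, an established human endometriotic epithelial cell line, after transfection with an siRNA against SMARCA4 (siBRG1) and after transfection with a non-targeting siRNA (control). SMARCA4 encodes BRG1, an ATPase of the SWI/SNF chromatin remodelling complexes. Each group held 3 libraries (n = 3), made 72 h after transfection with 50 nM siRNA. The labels mark all 3 control libraries as taken from an earlier deposit and analysed again. No siBRG1 library carries that mark, so batch and group cannot be told apart for any gene or list below. Counts assigned to genes came to 12749200 ± 539462 per siBRG1 library (SD, n = 3, range 12391200 to 13369700) and 43846100 ± 5132510 per control library (SD, n = 3, range 40228700 to 49720300). An exact two-sided permutation test of these totals gave p = 0.1, the smallest value that 3 libraries against 3 allow. At least 10 counts were found for 13863 ± 105 genes per siBRG1 library and 17118 ± 392 genes per control library (SD, n = 3). Gene expression is given below as CPM (counts relative to the TMM-normalised library total, mean ± SD, n = 3 per group), and log2 fold changes are siBRG1 over control with their standard error (SE). Adjusted p-values of single genes come from edgeR's quasi-likelihood test, and those of gene lists from camera. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

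The comparison asked which transcripts differ when BRG1 is depleted in endometriotic epithelial cells, in a series whose title speaks of lost epithelial integrity. SMARCA4 fell 4.07-fold. All 24 genes of cholesterol synthesis and uptake tested rose, among them HMGCS1, an enzyme at the entry of the mevalonate pathway (log2 fold change 3.16, SE 0.125). Interferon-stimulated genes, p53 targets, collagens and integrins rose more often than they fell, while 17 of 21 targets of YAP/TAZ fell and 3 rose, with the largest fall in F3, the coagulation initiator tissue factor (log2 fold change −3.05, SE 0.0576). With an estimated correlation none of these lists was called by camera (adjusted p = 0.191 for the cholesterol and p53 lists, and adjusted p = 0.334 for the interferon, collagen, integrin and YAP/TAZ lists). Members of the epithelial junction list went both ways, with CLDN1 up (log2 fold change 2.90, SE 0.0591) and TJP1 down (log2 fold change −1.58, SE 0.0423). Replication-dependent histone mRNAs and small non-coding RNAs were nearly lost from the siBRG1 libraries, and mitochondrial ribosomal RNA was nearly lost from the control libraries. For these losses a difference in library preparation cannot be told apart from the knockdown.

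SMARCA4 (ENSG00000127616.18, chromosome 19, 10960825 to 11079426 on GRCh38) was lower in each siBRG1 library, at 60.5, 78.9 and 50.6 CPM, than in any control library, at 244, 266 and 262 CPM. The means were 63.3 ± 14.4 CPM and 258 ± 11.8 CPM, a log2 fold change of −2.03 (SE 0.161, adjusted p = 0.000267). SMARCA2 (ENSG00000080503.23, chromosome 9, 1980290 to 2193624), which encodes BRM, the alternative ATPase of the complexes, stood at 53.4 ± 6.84 CPM against 52.0 ± 1.42 CPM and did not pass the test (log2 fold change 0.04, SE 0.0657, adjusted p = 0.599). With GC and length trends of each library removed, its log2 fold change was 0.41 (adjusted p = 2.37e-06), and without siBRG1 replicate 3 it was 0.14 (adjusted p = 0.0453). Of 27 SWI/SNF subunit genes tested, 16 fell and 6 rose, with the same counts adjusted over the list alone. The 16 include SMARCA4, the siRNA target, and the list was not tested without it. BCL7C rose most (log2 fold change 0.93, SE 0.0566). The 5 that did not pass were SMARCA2, SMARCB1, SS18L1, BICRAL and DPF2. The list's median log2 fold change was −0.24 (adjusted p = 0.0379, and adjusted p = 0.334 with an estimated correlation). Its call was also lost with a stricter count filter (adjusted p = 0.0595), with unstranded counts (adjusted p = 0.0733), with GC and length trends removed (adjusted p = 0.105) and without siBRG1 replicate 3 (adjusted p = 0.0599).

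**Figure D1:**
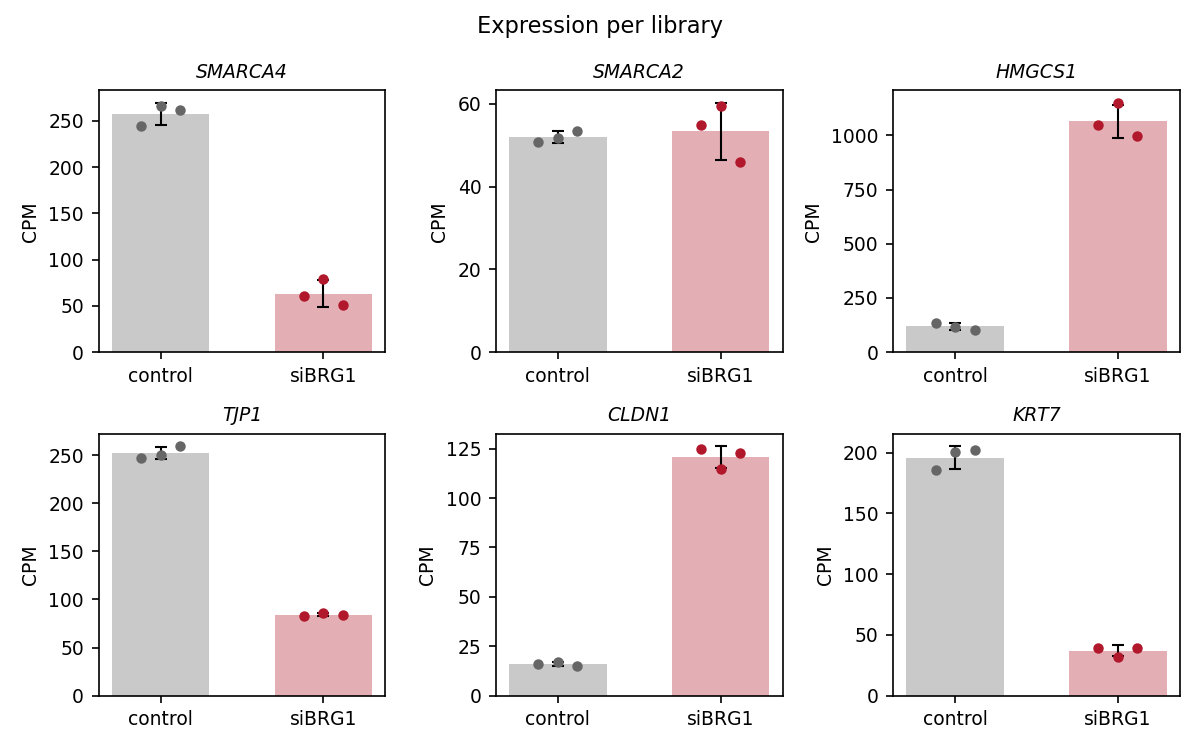
Expression of 6 genes in CPM (vertical axes, each from 0) in 3 control and 3 siBRG1 libraries; bars show the mean, error bars the SD and points the libraries. SMARCA4 lies between 50.6 and 78.9 CPM in the siBRG1 libraries and between 244 and 266 CPM in the control libraries.

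The groups also differed in the kinds of RNA their libraries held. MT-RNR2, the mitochondrial 16S ribosomal RNA gene (ENSG00000210082.2, mitochondrial genome, 1671 to 3229), had the largest rise by the rule for named genes, at 9247 ± 194 CPM in siBRG1 against 9.30 ± 11.3 CPM in control (log2 fold change 9.89, SE 1.09, adjusted p = 0.00121). Its control libraries stood at 21.8, 6.02 and 0.0497 CPM. MT-RNR1, the 12S gene, followed (log2 fold change 8.40, SE 0.802, adjusted p = 0.000704). Without control replicate 1 these log2 fold changes were 11.57 and 9.80. All 53 replication-dependent histone genes tested fell, with a median log2 fold change of −7.08. As a share of gene counts, all genes with HIST symbols, tested or not, made up 0.0172 ± 0.00125% in siBRG1 and 1.06 ± 0.0275% in control (SD, n = 3). Mitochondrial ribosomal RNA made up 1.16 ± 0.0340% and 0.00146 ± 0.00171%. HIST1H2AB had 2 counts over the 3 siBRG1 libraries and 18086 over the 3 control libraries, a ratio of 0.000361 (95% counting interval 4.37e-05 to 0.00130). Its fitted log2 fold change, which at 2 counts depends on the prior count, moved from −11.31 to −10.04 with GC and length trends removed. Of 83 small nucleolar RNA genes 78 fell, with a median log2 fold change of −3.81. The median was −3.44 with genes at 0 siBRG1 counts set to their bound and those at 1 to 3 to their count ratio. Of 31 spliceosomal-type small nuclear RNA genes 27 fell, with a median of −7.56, or −4.22 with genes treated the same way. In siBRG1 18 of the 31 had 0 counts, so −4.22 rests largely on bounds. All 5 small Cajal body RNA genes tested fell, with a median of −4.88. SCARNA21, RF00012, SNORD13, MIR3609 and AC007952.4 had 0 counts in all 3 siBRG1 libraries, which against a floor of 3 counts over the group made them at least 221-fold, 135-fold, 125-fold, 109-fold and 76.2-fold lower. Intervals and floors cover counting error only. Small nucleolar, nuclear and Cajal body RNAs, together with microRNA and miscellaneous RNA genes, took 0.00915 ± 0.00159% of gene counts in siBRG1 and 0.464 ± 0.0162% in control.

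Of 23 replication histones in the fixed list, 21 were tested and all 21 fell, with the same count adjusted over the list alone. HIST1H4B fell most (log2 fold change −10.05, SE 0.126, 11 counts over the siBRG1 libraries), followed by HIST1H4D (log2 fold change −9.99, SE 0.135). Single histone genes are near-identical copies, so their single values are uncertain. With GC and length trends removed these log2 fold changes were −8.82 and −8.23, without siBRG1 replicate 1 that of HIST1H4B was −10.88, and without siBRG1 replicate 2 that of HIST1H4D was −11.19. The list's median was −6.42 (adjusted p = 4.29e-17, and adjusted p = 0.191 with an estimated correlation). Of all reads, 3.97 ± 0.194% in siBRG1 and 13.3 ± 0.415% in control were assigned to no gene feature on their strand, which takes in intronic and antisense as well as intergenic reads, and 20.3 ± 1.62% and 9.81 ± 0.224% mapped to several places. For each of these shares the 3 siBRG1 libraries lay apart from the 3 control libraries (exact two-sided permutation p = 0.1, the smallest possible).

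**Figure D2:**
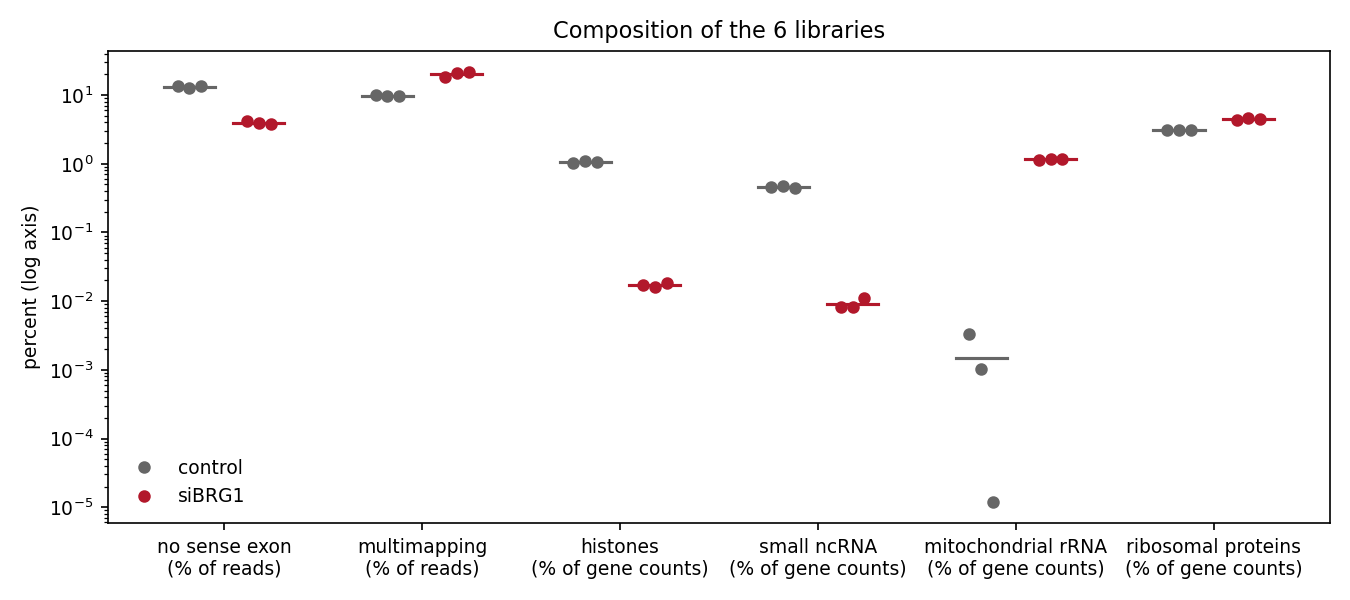
Share of reads or of gene counts in percent (log axis) taken by 6 kinds of sequence in each of 3 control and 3 siBRG1 libraries; points are libraries and lines the group means. Histones take 1.06% of gene counts in control and 0.0172% in siBRG1, while mitochondrial ribosomal RNA takes 0.00146% and 1.16%.

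At an adjusted p under 0.05, 11498 of 15830 genes tested differed between the groups, 5716 higher and 5782 lower in siBRG1. A change of at least 2-fold was found for 3412 genes, 1649 higher and 1763 lower. With a filter of at least 50 counts in 3 libraries that count was 2050. Protein-coding genes were also fitted alone, without histones and mitochondrial genes, which was chosen after the data were seen. In that fit 9697 of 12792 genes differed (75.8%), and 2066 did so at least 2-fold, 1221 higher and 845 lower. The labels put every control library in an earlier deposit and no siBRG1 library there, so each batch holds 1 group only. Batch and group cannot be told apart for any gene or list, above or below. Besides MT-RNR2 and MT-RNR1, the genes with the largest rises included LDHAP7, C3 and SCG2. C3, the central complement component, rose from 8.63 ± 1.28 to 136 ± 6.75 CPM (log2 fold change 3.98, SE 0.0710, adjusted p = 1.76e-27). SCG2, a secretogranin of neuroendocrine granules, rose by a log2 fold change of 3.42 (SE 0.107, adjusted p = 2.23e-21). LDHAP7 is a processed pseudogene of LDHA that can share its reads, so its log2 fold change of 4.47 (SE 0.168) is uncertain.

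Among 40 genes of epithelial adhesion, tight junctions, desmosomes and polarity, 28 were expressed highly enough to be tested. Of these 13 rose and 10 fell, with the same counts adjusted over the list alone. CLDN1, a claudin of tight junction strands (chromosome 3, 190305701 to 190322475), rose from 16.2 ± 1.12 to 121 ± 5.40 CPM (adjusted p = 5.35e-26). CDH3, which encodes P-cadherin, rose by a log2 fold change of 1.87 (SE 0.133, adjusted p = 4.32e-13). TJP1, which encodes the junction scaffold ZO-1 (chromosome 15, 29699367 to 29968865), fell from 252 ± 5.99 to 84.2 ± 1.77 CPM (adjusted p = 4.44e-23). PARD6B, a polarity complex gene, fell by a log2 fold change of −1.75 (SE 0.0988, adjusted p = 2.10e-15). Of genes singled out after their values were seen, CDH1, which encodes E-cadherin, rose from 3.05 ± 0.553 to 5.87 ± 1.35 CPM (log2 fold change 0.93, SE 0.185, adjusted p = 6.10e-05), and OCLN, which encodes occludin, fell from 22.7 ± 0.604 to 8.54 ± 0.864 CPM (log2 fold change −1.41, SE 0.0973, adjusted p = 1.99e-13). Among the 5 members that did not pass were ESRP2, CLDN3, PKP2 and PKP3. The list as a whole was not called by camera, with a median log2 fold change of 0.10 (adjusted p = 0.575), or −0.02 with no count filter (adjusted p = 0.636), and was called as higher by fry (adjusted p = 0.00133).

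Of 7 epithelial keratins tested, 5 fell and 1 rose, with the same counts adjusted over the list alone. KRT7 (chromosome 12, 52232520 to 52252186) fell from 196 ± 9.10 to 36.9 ± 4.50 CPM (log2 fold change −2.40, SE 0.0602, adjusted p = 9.51e-24), and KRT19, KRT80, KRT15 and KRT81 had log2 fold changes of −0.54, −0.88, −1.21 and −3.43. KRT81 had a mean below 50 counts, so the size of its fall is uncertain. KRT8 and KRT18, which pair in simple epithelia, were far more abundant. KRT18 stood at 1296 ± 93.0 against 1343 ± 22.9 CPM and did not pass (log2 fold change −0.05, adjusted p = 0.273). KRT8 rose by a log2 fold change of 0.09 (SE 0.0366, adjusted p = 0.0318), a call that was lost with GC and length trends removed (log2 fold change −0.01, adjusted p = 0.892). The call was also lost with DESeq2 size factors (adjusted p = 0.0813), with no count filter (adjusted p = 0.371), with protein-coding genes fitted alone (adjusted p = 0.232) and without siBRG1 replicate 3 or control replicate 1, 2 or 3 (adjusted p = 0.125 to 0.175). The keratin list had a median of −0.88 (adjusted p = 0.0175, and adjusted p = 0.334 with an estimated correlation), or −1.47 with no count filter.

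Mesenchymal genes and transcription factors of epithelial to mesenchymal transition went both ways, with 15 of 29 lower and 8 higher, also adjusted over the list alone. FOXC2 and TNC, which encodes the matrix protein tenascin-C, fell by 1.58 and 1.42 on the log2 scale (SE 0.165 and 0.0565), and POSTN, which encodes periostin, rose by 1.00 (SE 0.0885). Camera did not call the list (median −0.18, adjusted p = 0.101), but called it with no count filter (median −0.23, adjusted p = 0.0296), and fry called it (adjusted p = 0.000648).

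Targets and feedback genes of TGF-beta/SMAD signalling included 11 of 20 that fell and 8 that rose, with the same counts adjusted over the list alone. ID3, an inhibitor of bHLH factors, fell from 16.8 ± 0.774 to 2.90 ± 0.647 CPM (log2 fold change −2.54, SE 0.139), while LTBP2, a latent TGF-beta binding protein gene, rose by a log2 fold change of 1.80 (SE 0.0764). Camera did not call the list (median −0.58, adjusted p = 0.301), and fry called it as lower (adjusted p = 0.00767). Of 21 targets of YAP/TAZ and TEAD, 17 fell and 3 rose, also adjusted over the list alone. F3 fell from 250 ± 12.4 to 30.2 ± 2.89 CPM (adjusted p = 7.67e-27), and AMOTL1, a junction protein that binds YAP, rose by a log2 fold change of 0.55 (SE 0.0449). CTGF, an established YAP target also named CCN2 and singled out after its value was seen, was among the 3 that rose (log2 fold change 0.13, SE 0.0464), and ARHGEF17 was the other. YAP/TAZ targets had a median of −0.45 (adjusted p = 0.000110, and adjusted p = 0.334 with an estimated correlation), or −0.69 with GC and length trends removed. AP-1 and immediate early genes held 11 of 19 that rose and 6 that fell, with the same counts adjusted over the list alone. FOSL1, an AP-1 subunit, fell by a log2 fold change of −2.23 (SE 0.0586), and DUSP6, a phosphatase of ERK, rose by 1.45 (SE 0.0834). Neither camera (adjusted p = 0.379) nor fry (adjusted p = 0.0601) called that list (median 0.49).

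Of 31 collagen, laminin and basement membrane genes, 22 rose and 6 fell, with the same counts adjusted over the list alone. COL3A1, a fibrillar collagen gene, rose from 294 ± 33.7 to 1616 ± 98.3 CPM (log2 fold change 2.46, SE 0.0886, adjusted p = 3.37e-08), and COL7A1, the anchoring fibril collagen gene, fell from 3.27 ± 0.498 to 1.34 ± 0.298 CPM (log2 fold change −1.27, SE 0.243). COL3A1 is also among the markers of stromal fibroblasts, of which 8 of 13 rose (median 1.10, adjusted p = 0.0160, and adjusted p = 0.334 with an estimated correlation). Collagen and basement membrane genes had a median of 0.48 (adjusted p = 3.80e-05, and adjusted p = 0.334 with an estimated correlation). Of 15 integrin subunit genes tested, 10 rose and 2 fell, also adjusted over the list alone. ITGA11, a collagen receptor subunit gene, rose by a log2 fold change of 2.43 (SE 0.125), and ITGA6, a laminin receptor subunit gene, fell by 0.86 on the log2 scale (SE 0.0410). ITGB8 was the other integrin that fell, and ITGA2, ITGA4 and ITGA7 did not pass. The integrin median was 0.36 (adjusted p = 0.0190, and adjusted p = 0.334 with an estimated correlation). Matrix proteases and their inhibitors held 10 of 25 that rose and 9 that fell, with the same counts adjusted over the list alone. MMP2, a gelatinase gene, rose from 6.33 ± 0.608 to 59.7 ± 4.34 CPM (log2 fold change 3.23, SE 0.0823, adjusted p = 1.50e-23). MMP1, an interstitial collagenase gene, fell to 6 counts over the 3 siBRG1 libraries from 1298 counts over the control libraries (log2 fold change −6.00, SE 0.318, adjusted p = 5.21e-16). The siBRG1 libraries stood at 0.364, 0.0784 and 0 CPM, and the log2 fold change was −7.86 without siBRG1 replicate 1 and −7.85 with unstranded counts, so the size of this fall is uncertain. The protease median was 0.02 and the mean −0.41, and the list was called neither by camera (adjusted p = 0.877) nor by fry (adjusted p = 0.802).

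All 24 genes of cholesterol synthesis and uptake rose, 23 of them at least 2-fold, with the same count adjusted over the list alone; PMVK, at a log2 fold change of 0.87, was the exception. HMGCS1 (chromosome 5, 43289395 to 43313512) rose from 119 ± 16.4 to 1065 ± 77.8 CPM (log2 fold change 3.16, SE 0.125, adjusted p = 6.74e-06). The list's median log2 fold change was 2.03 (adjusted p = 7.92e-20, and adjusted p = 0.191 with an estimated correlation). Among 22 ATF4 and unfolded protein response genes, 10 fell and 6 rose, also adjusted over the list alone. SLC7A11, which encodes the cystine transporter subunit xCT, fell from 43.3 ± 2.64 to 5.82 ± 1.51 CPM (log2 fold change −2.89, SE 0.108), and DDIT4, an inhibitor of mTORC1 signalling, rose by a log2 fold change of 1.45 (SE 0.0708). That list was not called by camera (median −0.12, adjusted p = 0.397) and was called as lower by fry (adjusted p = 0.00281). Hypoxia and glycolysis genes held 10 of 24 that rose and 8 that fell, or 10 and 9 adjusted over the list alone. CA9, a carbonic anhydrase gene induced by HIF, rose by a log2 fold change of 2.07 (SE 0.140), and ADM, which encodes adrenomedullin, fell by 1.77 on the log2 scale (SE 0.0463). Hypoxia genes were not called as a list by camera (median 0.01, adjusted p = 0.575) and were called as higher by fry (adjusted p = 0.000691), with a median that changed sign between settings (−0.03 to 0.09).

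**Figure D3:**
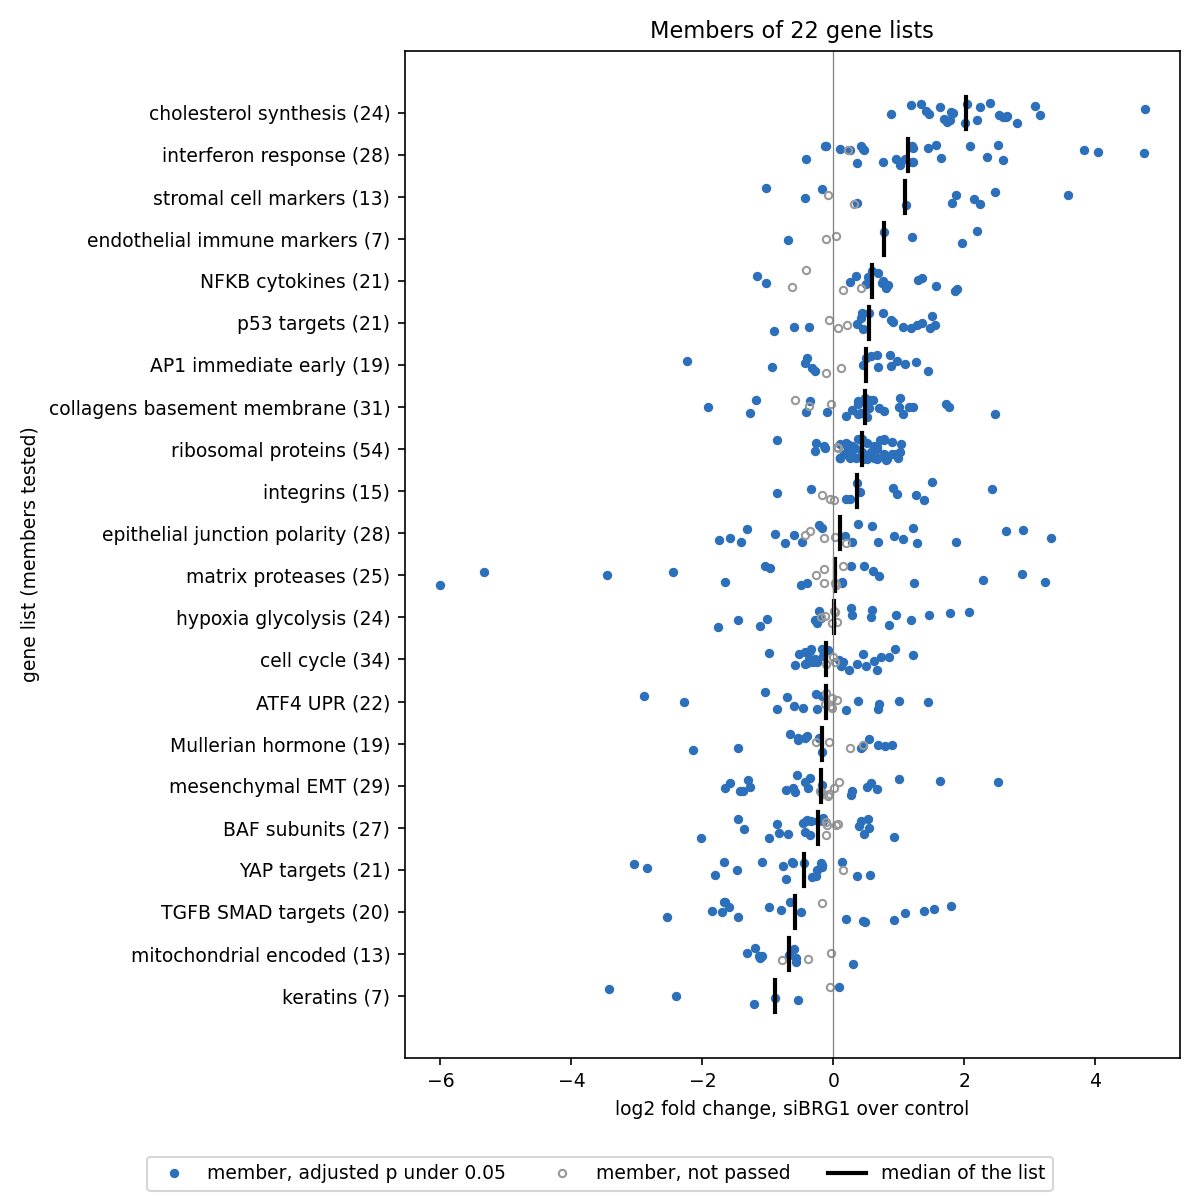
Log2 fold change, siBRG1 over control (horizontal axis), of the members of 22 fixed gene lists; points are genes, filled where the adjusted p was under 0.05, and black lines are list medians. The cholesterol list has the highest median of these lists, 2.03, and the keratin list the lowest, −0.88.

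Type I interferon stimulated genes rose in 24 of 28 cases and fell in 3, also adjusted over the list alone. OAS1, an antiviral oligoadenylate synthetase gene, rose from 0.529 ± 0.145 to 7.49 ± 1.42 CPM (log2 fold change 3.82, SE 0.237, adjusted p = 1.75e-14), or by 4.70 on the log2 scale at equal depth. IFIT5 fell by 0.41 on the log2 scale (SE 0.0622), SAMD9 and DTX3L fell by 0.13 and 0.11, and IRF7 did not pass. The interferon list had a median of 1.14 (adjusted p = 2.28e-05, and adjusted p = 0.334 with an estimated correlation). Of 21 cytokine and NF-kappaB feedback genes, 15 rose and 2 fell, with the same counts adjusted over the list alone. CCL2, a monocyte chemokine gene, rose from 5.01 ± 0.498 to 18.6 ± 2.51 CPM (log2 fold change 1.89, SE 0.119). The 2 that fell were IL11 (log2 fold change −1.17, SE 0.124) and TNFAIP3, a feedback inhibitor of the pathway (log2 fold change −1.03), and IL1A, IL1B, LIF and CXCL2 did not pass. The list had a median of 0.59 (adjusted p = 0.00526, and adjusted p = 0.334 with an estimated correlation).

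Direct p53 targets rose in 15 of 21 cases and fell in 3, also adjusted over the list alone. DDB2, a DNA damage recognition gene, rose by a log2 fold change of 1.55 (SE 0.0731), and CDKN1A, which encodes the cell cycle inhibitor p21 and was singled out after its value was seen, rose from 30.5 ± 2.45 to 85.3 ± 2.07 CPM (log2 fold change 1.48, SE 0.0590). MDM2, the feedback inhibitor of p53, fell by 0.91 on the log2 scale (SE 0.0489), SESN2 and AEN fell by 0.59 and 0.37, and BAX, ZMAT3 and SESN1 did not pass. The list's median was 0.54 (adjusted p = 0.00335, and adjusted p = 0.191 with an estimated correlation). Cell cycle genes of the S, G2 and M phases went both ways, with 13 of 34 higher and 18 lower, also adjusted over the list alone. CDK1 rose from 200.1 ± 4.59 to 465 ± 28.0 CPM (log2 fold change 1.22, SE 0.0412), and UHRF1, a DNA methylation maintenance gene, fell by 0.99 on the log2 scale (SE 0.0404). CCNA2, CCNB2 and CCNE1 did not pass. The cell cycle median was −0.12 and the mean 0.01, and the list was called neither by camera (adjusted p = 0.575) nor by fry (adjusted p = 0.563).

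Genes of Mullerian duct identity and steroid hormone response showed no common direction, with 6 of 19 higher and 9 lower, also adjusted over the list alone. WNT7B fell by a log2 fold change of −1.46 (SE 0.145). PAX8, a transcription factor of Mullerian epithelium, rose from 2.82 ± 0.0400 to 5.26 ± 0.263 CPM (log2 fold change 0.90, SE 0.167), but with unstranded counts its log2 fold change was −0.12 (adjusted p = 0.393). The list was called neither by camera (median −0.18, adjusted p = 0.852) nor by fry (adjusted p = 0.802). Markers of endometrial stromal fibroblasts, another cell type of the tissue of origin, rose for 8 of 13 genes and fell for 3, with the same counts adjusted over the list alone. COL3A1 rose most among those with at least 50 counts on average. LUM, which encodes lumican and was singled out after its value was seen, rose from 82.3 ± 8.75 to 389 ± 23.3 CPM (log2 fold change 2.24, SE 0.0655), and NR2F2, which encodes COUP-TFII, fell from 349 ± 14.6 to 171 ± 9.20 CPM (log2 fold change −1.03, SE 0.0429). WNT2 and THY1 also fell, and HAND2 and TCF21 did not pass. The stromal list had a median of 1.10 (adjusted p = 0.0160, and adjusted p = 0.334 with an estimated correlation), and its median was 0.69 with no count filter, 0.71 at equal depth and 0.73 without control replicate 3. Of 7 endothelial and immune markers tested, CD74, CDH5, CD14 and EGFL7 rose, VWF fell, and KDR and PTPRC did not pass, also adjusted over the list alone. CD74, the MHC class II invariant chain gene, rose from 2.41 ± 0.0890 to 11.1 ± 0.950 CPM (log2 fold change 2.20, SE 0.146). VWF had a log2 fold change of −0.69 (SE 0.282, adjusted p = 0.0301). Its call was lost without siBRG1 replicate 3 (log2 fold change −0.40, adjusted p = 0.209), without control replicate 2 (−0.63, adjusted p = 0.0898), without control replicate 3 (−0.68, adjusted p = 0.0705) and with DESeq2's Wald test (−0.71, adjusted p = 0.0507). Endothelial and immune markers were not called as a list by camera (median 0.77, or 0.37 with GC and length trends removed; adjusted p = 0.184) and were called as higher by fry (adjusted p = 0.000480).

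Transcripts that report on RNA quality and library type moved with the groups as well. Of 13 protein-coding mitochondrial transcripts, 9 fell and MT-ND3 rose, also adjusted over the list alone. MT-ND2 fell by a log2 fold change of −1.32 (SE 0.147, adjusted p = 0.00116), MT-ND3 rose by 0.31 (SE 0.0377), and MT-ATP8, MT-CYB and MT-ND4L did not pass. The median of the list was −0.68 (adjusted p = 0.000129, and adjusted p = 0.392 with an estimated correlation). With GC and length trends removed that median was −0.20 (adjusted p = 0.490) and the log2 fold change of MT-ND3 was 2.14. These trends were fitted over genes of all classes, histones included, so they cannot separate a length trend from a difference in RNA classes. Cytosolic ribosomal protein genes, which are short and abundant, rose in 47 of 54 cases and fell in 5, with the same counts adjusted over the list alone. RPS27 rose by a log2 fold change of 1.03 (SE 0.0453), and RPL10, which has many pseudogene copies and is uncertain, fell by 0.87 on the log2 scale (SE 0.179). The others that fell were RPL38, RPLP2, RPS13 and RPL14, and RPS3A and RPS19 did not pass. The ribosomal list had a median of 0.44 (adjusted p = 1.29e-12, and adjusted p = 0.334 with an estimated correlation). Of 23 lists 13 were called with the preset correlation, 8 up and 5 down. With an estimated correlation camera called 0 of them (3 at an unadjusted p under 0.05), and fry, which asks only whether a list's own genes move on balance in a single direction, called 19.

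The authors' deposited table listed 23148 genes, of which 12481 had an adjusted p under 0.05, 5722 higher and 6759 lower. In the authors' deposited table SMARCA4 had a log2 fold change of −2.05, TJP1 −1.61, CLDN1 2.88 and HMGCS1 3.13. By gene symbol, 15397 genes with an adjusted p in the authors' deposited table were also tested here. Of these, 10868 were called in both, 10837 in the same direction and 31 in the opposite direction. The log2 fold changes of the authors' deposited table and of the fit made here correlated at r = 0.870 across genes, which are not independent replicates. That table held 0 HIST symbols and no adjusted p for MT-RNR2. The HIST genes and MT-RNR2 therefore entered neither the overlap nor the correlation.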

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

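The tests on S phase genes, on the share of protein-coding genes past the threshold and on how many control libraries were not reused were chosen only after the results were seen. The list of structured RNAs without a poly(A) tail was also written after SNORD13 and SCARNA21 had been seen among the largest falls.

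In the reads that no gene count uses, the siBRG1 libraries stood above all control libraries in 2 shares. Reads mapped to several places made up 20.3% on average in siBRG1 (18.5 to 21.5%) against 9.81% in control (9.57 to 10.0%). Unmapped reads made up 1.84% (1.78 to 1.92%) against 1.64% (1.57 to 1.70%).

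Replication-dependent histones were lower in siBRG1, with a median log2 fold change of −7.08 over 53 genes. Histone variants with a poly(A) tail had a median of −0.016 (11 genes, −0.51 to 1.63), so poly(A) selection in the siBRG1 libraries against control libraries that kept RNA without a tail is a candidate explanation, although the labels state an mRNA kit for all samples. Of 16 structured RNAs without such a tail 7 were tested and fell, and leaving out SNORD13 and SCARNA21, which prompted the list, 5 of 14 were tested and fell (median −7.24, −9.92 to −4.66). The groups also lay apart in mitochondrial ribosomal RNA (1.16% of gene counts in siBRG1, 0.00146% in control). Reads assigned to no feature made up 3.97% of all reads in siBRG1 and 13.3% in control. Neither share entered the test on histone variants. Fewer cells in S phase would lower other S phase genes as well, but these had a median of 0.22 (20 genes, −0.43 to 0.94), and greater depth of the control libraries would not survive thinning to equal depth, after which the list of 21 replication histones had a median of −6.40 against −6.42 before. A smaller effect of BRG1 depletion on histone mRNA, on top of a difference in library type, stays open and untested.

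Cholesterol synthesis genes were higher in siBRG1, with a median log2 fold change of 2.03 over 24 genes. A trend with GC content or length is not the whole cause, since the median was 1.97 with these trends removed. Among 10000 random lists of protein-coding genes matched on expression, length and GC content, 0 reached the median of the real list, and the highest had a median of 0.92. That argues against a library effect of this size common to all such genes. Members of the random lists were drawn independently, so they cannot weigh a library effect on genes that are regulated together (estimated correlation within the real list 0.348). What cannot be told apart is an effect of BRG1 depletion from a culture, transfection or sequencing batch of the reused control libraries, because 0 control libraries are without that mark. Cell density, not given in the sources used here, could differ between batches, while the serum they give is the same for all 6 samples.

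The number of genes changed was 11498, or 72.6% of those tested. Depth is not the whole cause, since 10069 genes were called with all libraries thinned to equal depth, and RNA classes that poly(A) selection removes are not either, since 75.8% of protein-coding genes outside the histones were called when fitted alone. A difference in library preparation or batch that acts on coding genes cannot be told apart from the knockdown, because 0 control libraries are without the mark of reuse. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05: 1 split, the real one, gave 11498 genes, and edgeR called 0 in any other split (41 at most at an unadjusted p under 0.05). For genes changed at least 2-fold the real split gave 3412 and the highest other 0 (24 at most at an unadjusted p), and for gene lists called by camera it gave 13 and the highest other 11. Every other split mixes siBRG1 and control libraries, so the difference between the groups enters the spread within each side and leaves few genes to call. The contrast in gene numbers between splits therefore cannot show what chance would give.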

How the results depend on the processing

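The fit of protein-coding genes alone was chosen only after the data were seen. The cause of a change between settings was not tested unless stated. SMARCA4 was lower and called under every setting run for it, which leaves out limma voom (log2 fold change −2.07 to −1.96, and −2.21 to −1.89 with a library left out). The number of genes changed ran from 9697 (protein-coding genes alone, where fewer genes were tested) to 12541 (no count filter, where more were), and from 10291 to 11692 with a library left out. Of the 11498 calls, those that were also calls under another setting were compared in direction. Of these, 135 had the opposite direction with GC and length trends removed, 118 with the block as well, 35 with unstranded counts, and 0 under each other setting. Calls lost under a setting, as for KRT8 and PAX8 below, are not in these numbers. The share of calls that were higher ran from 44.2% (no filter, median of all genes −0.30) to 51.1%.

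Genes changed at least 2-fold numbered 3412 (1649 higher, 1763 lower) and moved by over 1.5 times with at least 50 counts in 3 libraries (2050, of which 1002 higher and 1048 lower), with protein-coding genes alone (2066, of which 845 lower) and with no filter (2844 lower). These settings test fewer or more genes by construction. With a library left out the number ran from 2813 to 3968. The number of lists called was 13, and 11 to 14 under the other settings, but 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 19 by fry.

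The epithelial list was called only by fry (median 0.10, adjusted p = 0.00133), its median was −0.02 with no filter, and camera gave it adjusted p = 0.366 to 0.816 over the other settings. The mesenchymal list was called by fry (median −0.18, adjusted p = 0.000648) and with no filter (median −0.23, adjusted p = 0.0296). Elsewhere camera gave it adjusted p up to 0.209 with the preset correlation and 0.386 with an estimated correlation. Medians of the protease and hypoxia lists, which were not called, changed sign between settings (−0.13 to 0.09 and −0.03 to 0.09). The direction camera gave also turned for the protease and cell cycle lists with unstranded counts (medians 0.0913 and −0.0701), and fry gave the other direction for the cell cycle and Mullerian lists (medians −0.12 and −0.18), with no call in any of these. Among named genes, the direction turned for KRT8 with GC and length trends removed (log2 fold change −0.0056, and −0.0063 with the block) and PAX8 with unstranded counts (−0.12). It also turned for SMARCA2, not called at 0.04, with no filter (−0.0051), at equal depth (−0.0126), with protein-coding genes alone (−0.0025) and with a library left out (−0.0395 to 0.136). Of the other values of named genes, 1101 kept direction and side of the threshold, 11 lost and 3 gained the call.

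The replicate numbers did not pair the samples, as same-numbered libraries deviated from their group means with r = −0.0126, 0.0220 and 0.00898, and not every library correlated best with its own number. With the number alone added as a block 11194 genes were called, and no call of a named gene or list changed. Depth limits the scarce RNAs most, since 3 counts stand for 0.230 CPM in an siBRG1 library and 0.0710 CPM in a control library.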

Other observations

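The choice of protein-coding genes below, the list of fatty acid genes and the list of LXR targets came only after FADS2, SCD and the cholesterol genes had been seen among the rises; the bounds for the tests on both lists were set before their values were seen.

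Among protein-coding genes outside the histones, chosen by the rule for named genes but after the data were seen, further large rises were those of FADS2 and SCD, which encode fatty acid desaturases, PDE7B, a cyclic AMP phosphodiesterase gene, and DIRAS3, an imprinted GTPase gene. FADS2 rose from 69.8 ± 6.0 to 740 ± 50.3 CPM (log2 fold change 3.40, SE 0.0569, adjusted p = 1.18e-22) and SCD from 250 ± 22.3 to 2295 ± 115 CPM (log2 fold change 3.20, SE 0.0533, adjusted p = 2.09e-25; SD, n = 3). PDE7B and DIRAS3 rose by 3.34 and 3.17 on the log2 scale (SE 0.112 and 0.113). After MMP1, the largest falls were those of PSG6 and PSG1 (log2 fold change −5.27 and −4.40), pregnancy-specific glycoprotein genes whose near-identical copies make single values uncertain. Without siBRG1 replicate 1 or 2 that of PSG1 was −3.78 or −5.04. CYP24A1, which encodes the enzyme that breaks down active vitamin D, fell from 181 ± 8.90 to 9.40 ± 0.536 CPM (log2 fold change −4.26, SE 0.0676, adjusted p = 9.41e-29). DIO2, a thyroid hormone deiodinase gene, fell from 31.6 ± 2.98 to 1.70 ± 0.317 CPM (log2 fold change −4.21, SE 0.141). MYPN, SERPINB2, which encodes PAI-2, and FOXQ1, a forkhead factor gene, fell by 4.16, 3.45 and 3.45 on the log2 scale (SE 0.120, 0.126 and 0.241).

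A hypothesis from FADS2 and SCD was that fatty acid synthesis genes, which SREBP factors also control, rose as a group. The other 17 members of that list had a median log2 fold change of 0.52, barely above the bound of 0.5 set beforehand, and 14 rose, among them FADS1 (2.27), ACSS2 (2.09), PNPLA3 (1.79) and FASN (1.76). ME1 fell (log2 fold change −0.51), and ELOVL1 and ACSL3 did not pass. The list was not set against other genes or against the cholesterol list in a test, and batch and knockdown cannot be told apart here either.

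A further hypothesis was less sterol in the siBRG1 cells, which would lower targets of the oxysterol receptor LXR. Of 5 targets tested, ABCA1 fell (log2 fold change −1.20, SE 0.0795) and MYLIP, LPCAT3, NR1H3 and SMPDL3A rose (0.91, 0.51, 1.58 and 0.55), with a median of 0.55. Set beforehand, a median above 0 was to count against the hypothesis, but the members went both ways (−1.20 to 1.58), and after the values were seen the test was judged too small to decide.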
